A study of Mus musculus with 18 samples.

How the data were processed

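Total RNA was measured in the nuclear fraction of C57BL/6 mouse embryonic stem cells, in 18 libraries. Per the labels, cells were grown with LIF, CHIR99021 and PD0325901 in serum. Actinomycin D, which stops transcription, was given at 5 µg/ml for 0, 3 or 6 h to cells cultured for 48 h. The nuclear fraction was isolated and its RNA purified. The authors added 0.1 µl of ERCC spike-in RNA to each sample before ribosomal RNA removal with RiboMinus, and made the libraries with the SMARTer stranded total RNA kit v2.

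The authors deposited raw read counts per gene for each library, as made by HTSeq, with no normalization. Their processing notes name CASAVA, Trimmomatic 0.38, HISAT2 2.1.0 and HTSeq with the mm10 genome, without options. The strand setting of HTSeq and the release of the gene models are not given in the sources used here, so counts of genes that overlap on opposite strands are uncertain. Each of the 18 count files holds 54446 genes, 92 spike-ins and 5 summary lines for reads not assigned to a gene. A table of all libraries held the same counts, with 0 cells differing. Gene symbols, biotypes and positions came from GENCODE M21, in which 54409 of the gene identifiers were found without their version and 53229 with it; 37 were not found. Reads that align to several places were counted by the authors as not unique and enter no gene, so families of near-identical genes (Zscan4, Usp17l, histones, Zfp genes, mitochondrial genes with nuclear copies) are measured on their unique parts alone.

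Gene reads per library ranged from 4950973 to 30989044, and spike-in reads from 3932 to 33396. Shares of reads carry 95% Wilson intervals, which cover counting error only, since reads were counted without molecular identifiers.

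The 12 Ythdc1 libraries (6 groups of 2) and the 6 Mettl3 libraries (3 groups of 2) were fitted separately. Each fit used edgeR 4.0.16 with 1 coefficient per group, TMM factors, the default expression filter (a minimum count of 10), robust quasi-likelihood dispersions and the quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg over all genes tested and called below 0.05. A further count needed a change of at least 2-fold. Decay differences are interaction terms: the change in libraries labelled cKO from 0 h, minus that in control libraries. Fold changes are relative to the typical gene of a library, since TMM sets the scale. All fold changes are on the log2 scale with their standard error (SE) and n = 2 libraries per group; levels are CPM, read counts scaled to library size and TMM factor, with their SD. Adjusted p-values of single genes come from edgeR throughout, and those of gene lists from camera in limma 3.58.1.

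Before the data were examined, 24 gene lists were fixed: m6A machinery, nuclear RNA decay, chromatin regulators, naive pluripotency, formative and primed pluripotency, 2-cell-like state, endoderm, mesoderm and primitive streak, neuroectoderm, trophoblast, fibroblast feeder, germline, imprinted genes, immediate early genes, p53 targets, integrated stress response, long noncoding RNAs, short noncoding RNA genes, housekeeping mRNAs, Hox clusters, replication-dependent histones, ribosomal proteins, mitochondrial mRNAs and Zfp zinc finger genes. Each was tested against the other genes with camera, two-sided, with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. The p-values were adjusted over the lists of a comparison. The rotation test fry was run beside it. Members passing were counted over all genes tested and adjusted over the list alone. The targeted genes Ythdc1 and Mettl3 were left out of every list.

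The genes named follow a rule fixed at the same time. It took Ythdc1 and Mettl3 always. It took the 8 highest and 8 lowest changes among called protein-coding or long noncoding genes with a mean of at least 50 counts, a regular symbol and no overlap between the groups' libraries. It took up to 4 called members of each list by p. The comparisons so treated were cKO against control at 0 h, control at 6 h against 0 h, the decay difference at 6 h, each Mettl3 knockout line and their mean. For the decay difference the condition of no overlap between libraries was dropped. Overlaps of calls were compared with independent lists and tested by Fisher's exact test, two-sided.

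The alternatives fixed at the same time were DESeq2 size factors, library size alone, scaling to spike-in reads, TMM from protein-coding nuclear genes, the DESeq2 1.42.0 Wald test, no filter, a filter of 50 reads in 2 libraries, a limit of 2-fold, a test against a fold change of 1.2, the replicate number as a block, 1 fit of all 18 libraries, fits of only the compared libraries, time as a linear term and each library left out in turn. Further alternatives were chosen after seeing the data: leaving out genes of chromosomes 6, 8, 14, 17, X and Y, leaving out the cKO 3 h libraries, using the 5 most abundant spike-ins only, and giving 1 Mettl3 control library to each knockout line, with the spread taken from the knockout lines. Replicate numbers were not treated as pairs: across genes, the residuals of libraries that share a replicate number correlated by at most 0.0426 in the 15 pairings of groups in the Ythdc1 experiment and by at most -0.00503 in the 3 of the Mettl3 experiment.

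The steps were tested on simulated data with 200 changed genes. For cKO against control at 0 h, 44.6%, 61.9% and 84.6% of genes changed by 1.5-, 2- and 4-fold were recovered, none with the wrong sign, and 3.27% of calls were false. For the decay difference at 6 h the shares recovered were 18.2%, 56.1% and 72.7%, with 12.5% of calls false. For the first Mettl3 line they were 53.9%, 74.2% and 90.6%, with 11.6% false, so the nominal 5% of false calls was exceeded in these 2 cases. A list raised 1.5-fold was found in each of the 3 cases. In each case 19 lists were run, and 0 of the others were called at the same threshold. Lists whose genes vary together were not tested in this way. The simulation therefore does not give the share of false list calls in the real data. Python 3.11.15 and R 4.3.3 were used. No library was left out of the main values.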

Results

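The series measured RNA of mouse embryonic stem cell nuclei in 9 groups of 2 libraries. It examines nuclear RNA decay without YTHDC1, the nuclear reader of N6-methyladenosine (m6A), and nuclear RNA without METTL3, the catalytic subunit of the m6A methyltransferase. Ythdc1 control cells and cells labelled cKO (conditional knockout) were taken after 0, 3 and 6 h of actinomycin D. A Mettl3 control and lines labelled KO1 and KO2 were taken without the drug.

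Gene reads in the Ythdc1 control numbered 8840925 and 12524328 at 0 h, 13287263 and 15012343 at 3 h, and 9638107 and 12239266 at 6 h. The libraries labelled cKO had 9088173 and 8723612 at 0 h, 14170524 and 19208935 at 3 h, and 4950973 and 17675289 at 6 h. The Mettl3 control had 20444256 and 22879403, KO1 30989044 and 23302028, and KO2 24895122 and 22714684. Reads outside annotated genes made up 18.02% to 53.5% of uniquely placed reads. Genes annotated as long noncoding RNA took 9.01% of control gene reads at 0 h (SD 0.280, n = 2), 1.80% at 3 h and 1.66% at 6 h. In the libraries labelled cKO they took 10.8% (SD 0.192), 2.17% and 1.87%. The gene Gm26917 carried most of this share at 0 h, 5.59% of control gene reads and 6.57% of those labelled cKO. Which RNA its reads come from was not tested, so the full share need not be long noncoding RNA. Without this gene the shares were 3.42%, 1.47% and 1.16% in control and 4.28%, 1.88% and 1.51% in cKO. Replicates differed by more than read sampling alone gives, with a chi-square per degree of freedom of 1.75 to 6.72, yet the biological coefficient of variation was 6.52% in the Ythdc1 and 4.09% in the Mettl3 experiment. The p-values below measure the spread between these libraries, which may not be separate cultures.

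Ythdc1 (ENSMUSG00000035851.14, mm10 chromosome 5, 86804221 to 86836659) was not lower in the libraries labelled cKO at 0 h. Its normalized level in counts scaled to library size (CPM) was 138.5 (SD 9.31, n = 2) in control and 131.8 (SD 16.1, n = 2) in cKO, a log2 fold change of -0.07 ± 0.079 (SE; adjusted p = 0.557). Without replicate 2 of cKO at 0 h the value was 0.05 (adjusted p = 0.764), and scaled to spike-ins it was -0.44 (adjusted p = 2.49e-05). After actinomycin D, Ythdc1 was 3.42-fold lower in cKO than in control at 3 h (log2 -1.78 ± 0.095, adjusted p = 1.13e-17) and 2.61-fold lower at 6 h (-1.38 ± 0.10, adjusted p = 1.08e-13). These values are with TMM. Scaled to spike-ins, the median decay difference of all genes was 2.36 at 3 h, against 0.0026 with TMM, and -0.087 at 6 h, against -0.034. The 3 h value therefore holds only relative to the typical gene. Mettl3 (ENSMUSG00000022160.18, chromosome 14, 52294841 to 52305128) was 34.3 (SD 3.32) in the Mettl3 control and 31.9 (SD 0.957) in KO1, a change of -0.10 ± 0.077 that did not pass the test (adjusted p = 0.316). In KO2 its level was 22.4 (SD 0.435), lower by a log2 fold change of -0.61 ± 0.081 (adjusted p = 7.45e-10). Scaled to spike-ins, Mettl3 was at 0.09 in KO1 (adjusted p = 0.403) and at -0.05 in KO2, where the call ended (adjusted p = 0.637). Counts per gene do not show whether part of a transcript is missing, so the group names below are those of the labels.

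**Figure D1:**
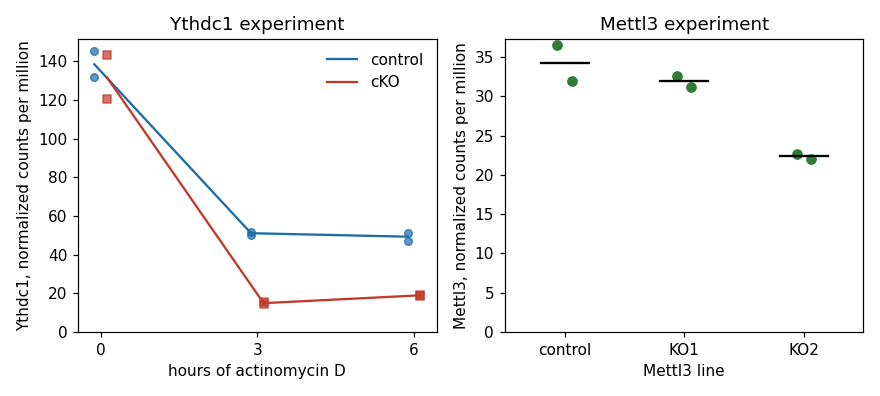
Normalized CPM of Ythdc1 against hours of actinomycin D (left) and of Mettl3 in each Mettl3 line (right). Points are libraries, 2 per group, and lines are group means; mean Ythdc1 is 138.5 and 131.8 in control and cKO at 0 h but 51.1 and 14.9 at 3 h.

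Libraries labelled cKO were compared with control at 0 h for the nuclear RNA that differs before transcription is stopped. Neat1, the long noncoding RNA that builds paraspeckles, rose from 210 to 859 CPM, a log2 fold change of 2.03 ± 0.064 (SE, n = 2 and 2; adjusted p = 2.9e-24). Malat1, a long noncoding RNA of nuclear speckles, rose by 0.71 ± 0.040. Among the protein-coding genes that rose most were Col20a1, a collagen (2.89 ± 0.18), Thbs1, which encodes thrombospondin (2.73 ± 0.25), the kinase gene Stk36 (2.58 ± 0.11), Nckap1l (2.36 ± 0.12) and the Notch ligand Dll1 (2.15 ± 0.22). The meiotic kinase gene Aurkc (-2.13 ± 0.23), the maternal factor Dppa3 (-2.03 ± 0.21), Itpka (-2.02 ± 0.15) and the cytokine gene Osm (-1.94 ± 0.28) fell, each with both cKO libraries below both controls.

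The 2-cell-like state list, genes of the early embryo that rare stem cells express, rose together: 18 of 24 measured members rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 0.95. Zscan4d rose by 1.55 ± 0.11, Usp17le by 1.46 ± 0.13 and Zscan4a, annotated as a pseudogene, by 0.94 ± 0.11. The camera test gave adjusted p = 5.35e-08, and adjusted p = 0.0136 with an estimated correlation; it was the only list of this comparison that passed both. Naive pluripotency genes fell, 16 of 25 with 2 rising (16 and 3 adjusted over the list alone; adjusted p = 0.000512, and adjusted p = 0.141 with an estimated correlation). They included Lin28a, which blocks let-7 maturation (-1.72 ± 0.14), the transcription factor gene Sall4 (-0.61 ± 0.049) and Tdgf1 (-0.40 ± 0.047). Of 26 p53 targets, 18 rose and 3 fell (19 and 5 adjusted over the list alone; adjusted p = 0.000112, and 0.0556 with an estimated correlation), among them Plk2 (0.97 ± 0.073), the p53 ubiquitin ligase gene Mdm2 (0.68 ± 0.058) and Ccng1 (0.65 ± 0.056); scaled to spike-ins, 9 p53 targets were higher and 8 lower, with a median of 0.015.

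Of 25 imprinted genes, 10 rose and 2 fell (11 and 3 adjusted over the list alone), with a median of 0.19 that turned to -0.18 when scaled to spike-ins; H19 rose by 1.76 ± 0.16, Peg10 by 1.51 ± 0.062 and Peg3 by 0.87 ± 0.053. Of 22 immediate early genes, 9 rose and 2 fell (11 and 2 adjusted over the list alone), including Jun (1.73 ± 0.16) and Btg2 (0.80 ± 0.095). Scaled to spike-ins, 5 imprinted genes were higher and 10 lower, and 5 and 4 immediate early genes. Both lists had adjusted p = 0.00685, with adjusted p = 0.11 and 0.177 with an estimated correlation. Ribosomal protein genes fell in 44 of 81 cases and rose in 1 (47 and 1 adjusted over the list alone; median -0.19, adjusted p = 2.57e-07, and 0.196 with an estimated correlation), as with Rps2 (-0.38 ± 0.049) and Rpl3 (-0.34 ± 0.046). Housekeeping mRNAs fell in 13 of 19 cases and rose in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.000512, and 0.254 with an estimated correlation), including Ldha (-0.51 ± 0.046). Replication-dependent histones fell in 16 of 62 cases and rose in 2 (the same counts adjusted over the list alone), and Hox genes fell in 2 of 9. Both lists had adjusted p = 0.027, with 0.227 and 0.177 with an estimated correlation. Scaled to spike-ins, the counts up and down were 1 and 48 for histones, 0 and 4 for Hox genes and 1 and 73 for ribosomal proteins. They were 0 and 19 for housekeeping mRNAs, 0 and 22 for naive pluripotency and 15 and 2 for the 2-cell-like list.

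The other lists were not called. Of 27 long noncoding RNAs, 12 rose and 4 fell (adjusted p = 0.102), but 4 were higher and 12 lower when scaled to spike-ins. Of 10 fibroblast feeder markers, 3 rose and 1 fell, with a median of 1.16 (adjusted p = 0.106). Of 23 nuclear RNA decay genes, 1 rose and 5 fell, among them the exosome gene Exosc5 (-0.69 ± 0.082). Of 22 m6A machinery genes, 4 rose and 5 fell, including the readers Igf2bp3 (-0.54 ± 0.070) and Ythdf1 (-0.50 ± 0.071). Chromatin regulators had 5 up and 9 down of 32: the demethylase gene Tet1 rose by 0.58 ± 0.045, while the H3K9 methyltransferase gene Ehmt2 (-0.95 ± 0.087), the DNA methyltransferase gene Dnmt3a (-0.65 ± 0.067) and the corepressor gene Trim28 (-0.53 ± 0.050) fell. Germline genes had 5 up and 4 down of 18, with Dazl at -1.08 ± 0.080 and Stra8 at -0.85 ± 0.10. The integrated stress response had 4 up and 5 down of 20, with the asparagine synthetase gene Asns at -0.80 ± 0.050 and Phgdh at -0.67 ± 0.082. Zfp genes had 49 up and 30 down of 338, with Zfp871 at 1.00 ± 0.074 and Zfp710 at -0.85 ± 0.079, and 13 up and 137 down when scaled to spike-ins. Formative and primed pluripotency had 5 up, including Dnmt3l (0.71 ± 0.079), and 2 down of 17. Short noncoding RNA genes had 4 up, including Scarna6 (0.58 ± 0.072), and 0 down of 15. Mitochondrial mRNAs had 2 up and 0 down of 10, and neuroectoderm 4 and 1 of 10. Mesoderm and primitive streak had 2 up and 1 down of 10, trophoblast 2 and 2 of 11, and endoderm 2 and 4 of 15. Adjusted over the list alone, the counts up and down of these lists were the same except for neuroectoderm (5 and 1), the integrated stress response (5 and 6), mitochondrial mRNAs (1 and 0) and Zfp genes (46 and 28). Scaled to spike-ins, the counts up and down were 0 and 19 for m6A machinery, 0 and 22 for nuclear RNA decay, 1 and 28 for chromatin regulators, 0 and 6 for germline, 3 and 9 for the integrated stress response, 3 and 7 for formative and primed pluripotency, 2 and 3 for short noncoding RNA genes, 0 and 0 for mitochondrial mRNAs, 1 and 2 for neuroectoderm, 0 and 1 for mesoderm and primitive streak, 1 and 3 for trophoblast, 1 and 6 for endoderm and 3 and 2 for feeder markers.

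Over all genes, 5255 of 17900 changed, 2425 higher and 2830 lower, of which 689 and 324 by at least 2-fold. Mettl3 was called slightly higher (0.27 ± 0.10, adjusted p = 0.0404), a call lost without each of 3 of the libraries, with most other settings and with spike-in scaling, which turned it to -0.10. Scaled to spike-ins, 8361 genes changed, 790 higher and 7571 lower, with the median of all genes at -0.35; without replicate 2 of control at 0 h, 3486 changed. Tested against a 1.2-fold change, 2324 passed, and Rpl3 did not (adjusted p = 0.099).

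Control libraries at 6 h of actinomycin D were compared with 0 h for the nuclear RNAs that are lost or kept once transcription stops. Replication-dependent histone RNAs fell in 61 of 62 cases (62 adjusted over the list alone), with a median of -3.98; examples were Hist1h2ah (-6.56 ± 0.27), Hist1h1d (-4.67 ± 0.092) and Hist1h1a (-3.75 ± 0.071). Of 338 Zfp genes, 262 fell and 15 rose (265 and 16 adjusted over the list alone; median -1.42), as with Zfp26 (-2.94 ± 0.092) and Zfp292 (-2.02 ± 0.062). Of 26 p53 targets, 22 fell and 2 rose (22 and 3 adjusted over the list alone), including Plk2 (-2.27 ± 0.089) and Mdm2 (-1.63 ± 0.061). These 3 lists also passed with an estimated correlation, at adjusted p = 0.00568, 0.00919 and 0.0272.

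Immediate early genes fell in 13 of 22 cases and rose in 3 (median -1.05; adjusted p = 0.00097, and 0.111 with an estimated correlation), with the matricellular protein gene Ccn1 at -5.44 ± 0.26 and Ccn2 at -2.64 ± 0.099. Spry4, a feedback inhibitor of FGF signalling, fell by 5.05 ± 0.38. Long noncoding RNAs fell in 18 of 27 cases and rose in 4 (adjusted p = 0.000112, and 0.2 with an estimated correlation), including Neat1 (-2.35 ± 0.071) and the snoRNA host gene Gas5 (-2.27 ± 0.078); Kcnq1ot1, an imprinted antisense RNA, fell by 2.38 ± 0.054. All 10 mitochondrial mRNAs, which are not nuclear RNAs, fell (median -2.98; adjusted p = 2.2e-05, and 0.217 with an estimated correlation), including mt-Nd1 (-4.64 ± 0.21) and mt-Cytb (-3.75 ± 0.074). Of 22 m6A machinery genes, 13 fell and 3 rose (adjusted p = 0.0295, and 0.217 with an estimated correlation), with the methyltransferase subunit gene Wtap at -2.22 ± 0.088; Ythdc1 (-1.49 ± 0.085) and Mettl3 (-0.56 ± 0.11) fell. The 2-cell-like list fell in 12 of 24 cases and rose in 0 (adjusted p = 0.0104, and 0.0936 with an estimated correlation). Scaled to spike-ins, 23 genes of this list were lower and 0 higher, and 22 and 0 of the m6A machinery. Naive pluripotency genes, not called as a list, ranged from Fgf4 (-2.97 ± 0.074) and Klf2 (-2.35 ± 0.10) to Dppa5a (1.82 ± 0.055).

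Relative to the typical gene, ribosomal protein RNAs rose in 70 of 81 cases and fell in 5 (median 1.01; adjusted p = 1.14e-14, and 0.0936 with an estimated correlation), Rpl38 by 2.53 ± 0.064 and Rps16 by 2.22 ± 0.057. Housekeeping mRNAs rose in 16 of 19 cases and fell in 2 (adjusted p = 0.000112, and 0.217 with an estimated correlation), Hsp90ab1 by 1.16 ± 0.034 and Eef2 by 1.12 ± 0.039. Scaled to spike-ins, 33 ribosomal protein RNAs were higher and 27 lower (median 0.090), and 10 and 8 housekeeping mRNAs (median 0.14). Short noncoding RNA genes rose in 10 of 15 cases (adjusted p = 0.000742, and 0.281 with an estimated correlation), with Scarna6 at 2.70 ± 0.071 and Rn7sk at 0.91 ± 0.033, which turned to -0.0049 and lost its call when scaled to spike-ins. Endoderm genes rose in 6 of 15 cases (median 0.77, turned to -0.14 when scaled to spike-ins; adjusted p = 0.0311, and 0.281 with an estimated correlation), as with Sparc (1.58 ± 0.051). Fibroblast feeder markers, not called as a list (adjusted p = 0.0977), also rose in 6 of 10 cases and fell in 0, with a median of 1.34, or in 2 with a median of 0.42 when scaled to spike-ins. Platr15 (3.96 ± 0.23), Kifc2 (2.62 ± 0.15) and Abca7 (2.52 ± 0.088) rose, Trim28 rose by 1.33 ± 0.051, and Atf4 fell by 1.46 ± 0.074. For lists of this comparison with no such count given, those adjusted over the list alone were the same as over all genes, except that 4 m6A machinery genes rose.

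In all, 11602 of 17900 genes changed in control at 6 h, 5919 higher and 5683 lower, and 5885 of them by at least 2-fold. Scaled to spike-ins, 12596 changed, 1312 higher and 11284 lower, with the median of all genes at -0.88, so that a rise here is relative to other RNA. With library size alone 4701 were higher and 6831 lower, with a median of -0.16. At 3 h, 10107 genes had changed, 5253 higher and 4854 lower (3506 by at least 2-fold), and 1287 and 9147 when scaled to spike-ins, with a median of -0.46. Histones already fell in 61 of 62 cases at 3 h (median -2.94; adjusted p = 0.00337 with an estimated correlation) and Zfp genes in 258 of 338, with 14 rising (261 and 14 adjusted over the list alone; median -0.89; 0.00767).

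In libraries labelled cKO the same groups fell over 6 h: 59 of 62 histones (median -3.21; adjusted p = 0.00735 with an estimated correlation) and 248 of 338 Zfp genes, with 14 rising (250 and 14 adjusted over the list alone; median -0.95; 0.016). Ribosomal protein RNAs rose in 76 of 81 cases and fell in 3 (median 1.16; 0.0432), with 39 higher and 17 lower when scaled to spike-ins (median 0.19), and 9 of 10 mitochondrial mRNAs fell (9, with 1 rising, adjusted over the list alone; median -2.81; 0.326). Over all genes, 10908 changed at 6 h, 5298 higher and 5610 lower (4959 by at least 2-fold). Of the genes called at 6 h in both genotypes, 8701 moved the same way and 208 the opposite way. At 3 h, 10640 changed, 5299 higher and 5341 lower (4115 by at least 2-fold); histones fell in 61 of 62 cases (median -2.90; adjusted p = 0.00527 with an estimated correlation), and Zfp genes fell in 220 of 338 cases and rose in 13, their median of -0.66 turning to 1.18 when scaled to spike-ins. Scaled to spike-ins, 587 genes were higher and 12249 lower at 6 h, with a median of -0.96, but 14992 were higher and 482 lower at 3 h, with a median of 1.86. That scaling rests on a spike-in share that stood apart in the cKO 3 h libraries.

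**Figure D2:**
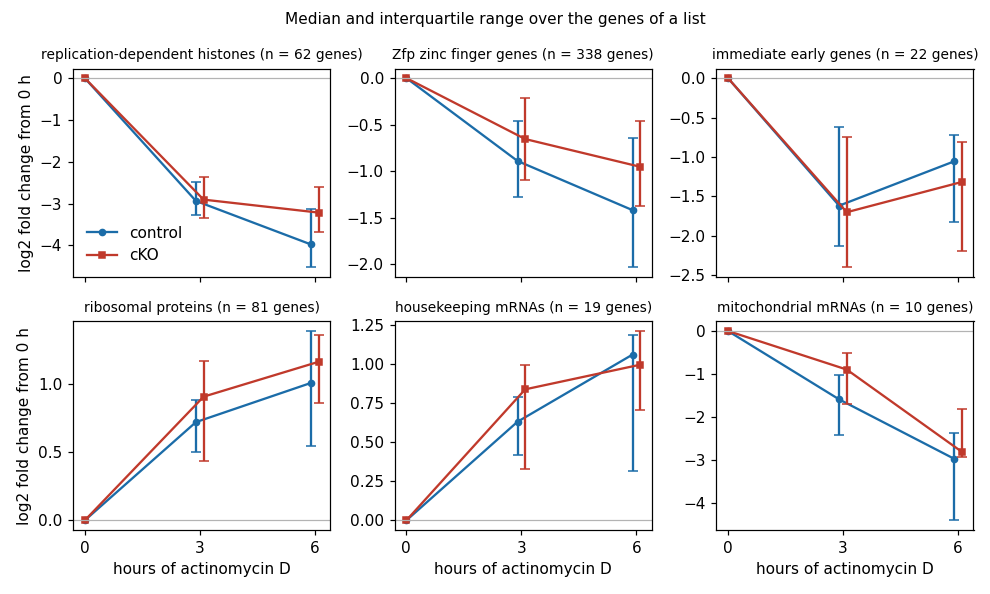
Median log2 fold change from 0 h against hours of actinomycin D for 6 gene lists, in control and cKO, scaled by TMM. Bars are the interquartile range over the genes of a list; the histone median at 6 h is -3.98 in control and -3.21 in cKO. Scaled to spike-ins, the cKO medians at 3 h of Zfp genes, immediate early genes and mitochondrial mRNAs turn positive.

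The decay difference at 6 h asks which RNAs changed differently over 6 h in cKO and control; positive values mean that an RNA fell less, or rose more, in cKO. Replication-dependent histones fell less in cKO: 25 of 62 were called positive and 0 negative (29 and 0 adjusted over the list alone), with a median of 0.77 (adjusted p = 5.15e-10, and 0.0497 with an estimated correlation). Hist1h2ah went from 38.6 to 0.383 CPM in control but from 23.3 to 2.18 in cKO, a difference of 3.26 ± 0.46, and Hist1h4h had a difference of 1.41 ± 0.17. The control level of Hist1h2ah at 6 h rests on few reads, in libraries of 9638107 and 12239266 gene reads. Of 338 Zfp genes, 80 were positive and 8 negative (91 and 9 adjusted over the list alone; median 0.34, adjusted p = 6.86e-08, and 0.0914 with an estimated correlation), with Zfp748 at 2.25 ± 0.21 and Zfp961 at 1.26 ± 0.12. Fgf4 fell from 373 to 47.5 in control and from 281 to 87.3 in cKO (1.29 ± 0.10). Fgf4 and Hist1h2ah thus began at lower levels in cKO, and at 0 h 16 histones were called lower and 2 higher. The libraries of 0 h enter this difference, so positive values need not mean slower decay. Spry4 (2.84 ± 0.52), the snoRNA host gene Snhg3 (1.48 ± 0.15), Dppa2 (0.87 ± 0.099) and Eda2r (0.80 ± 0.11) were also positive.

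Neat1 fell more in cKO, from 859 to 65.1 against 210 to 41.3 in control (-1.38 ± 0.097). It was already at 74.0 in cKO and 52.3 in control at 3 h. Jun was 23.7 and 25.1 at 0 and 6 h in cKO but 7.11 and 21.6 in control (-1.52 ± 0.21). Both genes were higher in cKO at 0 h, whose libraries enter this difference, so their negative values need not mean faster decay. The same holds for Scarna6, also higher in cKO at 0 h. Pck2, the mitochondrial PEP carboxykinase gene (-1.83 ± 0.24), Snx29 (-1.47 ± 0.16), Scarna6 (-1.08 ± 0.097), the methyltransferase complex gene Zc3h13 (-1.03 ± 0.10) and Ythdc1 itself (-1.31 ± 0.13) were negative, while Mettl3 was at -0.14 ± 0.15 (adjusted p = 0.59). Of 10 mitochondrial mRNAs, 5 were positive (median 1.24; adjusted p = 0.00246, and 0.507 with an estimated correlation), with mt-Nd1 at 1.70 ± 0.26 and mt-Cytb at 0.96 ± 0.096. All mitochondrial genes together took 3.01% of gene reads in cKO and 1.17% in control at 6 h. Carry-over into the nuclear fraction and slower decay cannot be told apart here. Ribosomal proteins had 28 positive, including Rpl31 (1.06 ± 0.092), and 10 negative of 81 (32 and 12 adjusted over the list alone), and endoderm genes 0 positive and 6 negative of 15 (0 and 7 adjusted over the list alone), including the collagen gene Col4a1 (-0.96 ± 0.11); fibroblast feeder markers, not called as a list (adjusted p = 0.17), had 0 positive and 2 negative of 10, with a median of -0.69. Ribosomal proteins and endoderm genes both had adjusted p = 0.0156, with 0.653 and 0.419 with an estimated correlation. In all, 3422 genes differed, 1749 positive and 1673 negative, and 648 by at least 2-fold. Library size alone gave 2938 positive and 993 negative, with a median of 0.11, and spike-in scaling 1346 and 1851. Time as a linear term left 41 calls, ending those of Ythdc1, Hist1h2ah, Hist1h4h, Spry4, Fgf4, Dppa2, Snhg3, Neat1, Jun, Scarna6, mt-Cytb, Rpl31, Col4a1 and Eda2r, although their fitted differences over 6 h kept their sign and most stayed close (-1.40 for Ythdc1, 3.29 for Hist1h2ah, 1.30 for Fgf4 and -1.39 for Neat1, but 4.61 for Spry4). At 6 h 1571 genes passed against a 1.2-fold change. Lists called numbered 5, and 8 in a fit of all 18 libraries.

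At 3 h, 3476 genes had a decay difference, 1974 positive and 1502 negative, 409 of them by at least 2-fold, and 1433 passed against a 1.2-fold change. Zfp genes had 57 positive and 16 negative of 338 (58 and 18 adjusted over the list alone; median 0.21, adjusted p = 0.00297, and 0.616 with an estimated correlation). Histones had 11 positive and 9 negative of 62 and were not called (adjusted p = 0.717). Scaled to spike-ins, 15997 genes were positive and 0 negative, with a median of 2.36. Genes called at 0 h were then followed from 3 to 6 h, which uses no library from 0 h. The 2425 genes higher in cKO at 0 h had a median difference in this later decay of -0.020, against -0.012 for genes not called; the camera test, whose direction was opposite to that median, did not pass (adjusted p = 0.772), so slower later decay was not detected. The 2830 genes lower at 0 h had a median of -0.10 (adjusted p = 0.0279, and 0.514 with an estimated correlation). With no filter on low counts the higher genes lay 0.083 above genes not called and passed the test.

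Mettl3 KO1 was compared with the Mettl3 control for nuclear RNA in the first knockout line. Sp5, a target of WNT signalling, rose from 0.348 to 11.7 CPM, a change of 5.09 ± 0.26 (SE, n = 2 and 2; adjusted p = 1.67e-29). Lef1, a transcription factor gene of the same pathway, rose by 3.21 ± 0.27, the ligand gene Wnt5b by 3.09 ± 0.14, Nkx1-2 by 4.91 ± 0.34 and Bach2 by 2.97 ± 0.17. Meg3 (-3.08 ± 0.045), Mirg (-2.75 ± 0.069) and Rian (-2.72 ± 0.041), maternally expressed long noncoding RNAs of the imprinted Dlk1 region, fell, as did Dlk1 itself (-2.96 ± 0.31) and H19 (-2.66 ± 0.16). Id1, a target of BMP signalling (-3.08 ± 0.11), and the receptor gene Chrm1 (-3.16 ± 0.32) fell, and Myc rose by 2.22 ± 0.11. Ythdc1 was lower, by a change of -0.34 ± 0.037.

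Imprinted genes fell in 17 of 28 cases and rose in 2 (18 and 3 adjusted over the list alone; adjusted p = 0.000151, and 0.156 with an estimated correlation); Grb10 rose by 2.09 ± 0.049. The 2-cell-like list fell in 19 of 25 cases and rose in 0 (20 and 0 adjusted over the list alone; median -1.32, adjusted p = 5.63e-08, and 0.156 with an estimated correlation), as with Usp17le (-2.16 ± 0.18) and Pramel7 (-2.06 ± 0.12). Naive pluripotency genes rose in 19 of 25 cases and fell in 4 (the same adjusted over the list alone; adjusted p = 0.00203, and 0.156 with an estimated correlation), Tfcp2l1 by 1.00 ± 0.029, Nr0b1 by 0.90 ± 0.050 and Nr5a2 by 0.87 ± 0.041, while Klf2 fell by 1.01 ± 0.049. Trophoblast genes fell in 9 of 12 cases and rose in 1 (adjusted p = 0.00091), germline genes fell in 9 of 18 and rose in 1, including Tex14 (-1.21 ± 0.073) and Dazl (-0.98 ± 0.10; adjusted p = 0.00215 for the list), and endoderm genes fell in 8 of 18 and rose in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.0092). With an estimated correlation their adjusted p = 0.156, 0.222 and 0.319. Histones rose in 42 of 61 cases and fell in 1 (43 and 1 adjusted over the list alone), such as Hist1h1d (0.61 ± 0.033), ribosomal proteins rose in 58 of 81 and fell in 8 (59 and 9), such as Rps20 (0.63 ± 0.031), housekeeping mRNAs rose in 18 of 19 and fell in 0 (19 and 0) and mitochondrial mRNAs rose in 8 of 12 and fell in 0 (8 and 0), such as mt-Nd5 (0.57 ± 0.033). Their adjusted p = 5.63e-08, 1.06e-07, 8.23e-08 and 0.0026, and 0.156, 0.39, 0.179 and 0.537 with an estimated correlation.

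Among lists not called in KO1, the integrated stress response held Herpud1 at -2.17 ± 0.082 and Shmt2 at 0.98 ± 0.040, chromatin regulators Atrx at 1.26 ± 0.027 and Tet1 at 0.51 ± 0.027, and Zfp genes Zfp981 at 1.73 ± 0.045 and Zfp600 at 1.72 ± 0.049. The lines also differed by chromosome: the median of 809 protein-coding genes on chromosome 8, which holds Klf2 and Herpud1, was -0.51 in KO1, with other autosomes between 0.00 and 0.16. The Y-linked gene Kdm5d was higher by 3.39 ± 0.27. In all, 10040 of 21802 genes changed, 5209 higher and 4831 lower, and 2228 by at least 2-fold; 5793 passed against a 1.2-fold change. Scaled to spike-ins, 7585 were higher and 2985 lower, with the median of all genes at 0.17. Without replicate 1 of the Mettl3 control, the change of Mettl3 was 0.0025.

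In KO2 against the same control, Sp5 rose by 5.21 ± 0.26 (adjusted p = 2.07e-30) and Lef1 by 3.02 ± 0.28, while Id1 (-3.93 ± 0.13) and Chrm1 (-4.38 ± 0.39) fell. Mir124a-1hg, the host gene of a neuronal microRNA (-4.10 ± 0.089), Prph, a neuronal intermediate filament gene (-3.87 ± 0.20), the meiotic gene Stra8 (-3.34 ± 0.22) and the imprinted gene Mest (-2.33 ± 0.057) fell. Rian fell by 0.88 ± 0.037. Ido2 (4.57 ± 0.22), Bglap3 (4.07 ± 0.18), the RNA-binding protein gene Igf2bp2 (1.74 ± 0.066), Atrx (1.247 ± 0.027), Dnmt3b (1.17 ± 0.047) and Zfp981 (1.98 ± 0.045) rose. Ythdc1 was lower, by a change of -0.75 ± 0.038, and Malat1 fell by 0.59 ± 0.020, a call that ended when scaled to spike-ins (-0.03, adjusted p = 0.374).

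Fibroblast feeder markers rose in 7 of 11 cases and fell in 0, with a median of 1.18 (adjusted p = 0.000598, and 0.534 with an estimated correlation). They included the smooth muscle actin gene Acta2 (2.52 ± 0.070) and the collagen genes Col1a1 (1.40 ± 0.041) and Col1a2 (1.18 ± 0.048). Col1a1 stood at 103 CPM in the Mettl3 control and 272 in KO2, against 1.70 in the Ythdc1 control at 0 h. A different share of feeder cells and a change within the stem cells cannot be told apart. Naive pluripotency genes fell in 16 of 25 cases and rose in 3, as with Prdm14 (-1.68 ± 0.076), Zfp57 (-0.88 ± 0.032) and Fgf4 (-0.84 ± 0.032) against Tfcp2l1 (0.71 ± 0.029), and their median of -0.19 turned to 0.38 when scaled to spike-ins (adjusted p = 0.0124, and 0.534 with an estimated correlation). All 12 mitochondrial mRNAs rose (median 1.22; adjusted p = 3.7e-05, and 0.534 with an estimated correlation), mt-Nd5 by 1.34 ± 0.034 and mt-Nd4 by 1.27 ± 0.070. All mitochondrial genes together took 3.68% of gene reads in KO2 and 1.02% in control. Carry-over into the nuclear fraction and a change of these mRNAs in the cells cannot be told apart. Germline genes fell in 10 of 18 cases and rose in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.0388), or 6 of 18 with 6 rising when scaled to spike-ins, and histones rose in 24 of 61 and fell in 5 (23 and 5 adjusted over the list alone; adjusted p = 0.0464), or 52 and 1 when scaled to spike-ins and 19 and 6 with library size alone. Both had adjusted p = 0.534 with an estimated correlation. The counts of the first 3 lists were the same adjusted over the list alone. Chromosome medians were -0.44 for chromosome 8, which holds Ido2, and -0.42 for chromosome 6, which holds Mest, Stra8 and Col1a2, -0.25 for chromosome 14, which holds Mettl3, -0.21 for chromosome 17 and -0.20 for chromosome 4; the highest autosome was at 0.22. The Y-linked genes Kdm5d (4.87 ± 0.24) and Zfy1 (4.50 ± 0.24) were higher. In all, 11079 genes changed, 5317 higher and 5762 lower, and 3380 by at least 2-fold; 7178 passed against a 1.2-fold change. Scaled to spike-ins, 12359 were higher and 1458 lower, with a median of 0.53. The number of lists called fell to 3 without replicate 2 of the Mettl3 control, without replicate 1 of KO2 and with library size alone, rose to 8 with spike-in scaling, and fell to 2 without the genes of chromosomes 6, 8, 14, 17, X and Y, an alternative chosen after seeing the data.

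**Figure D3:**
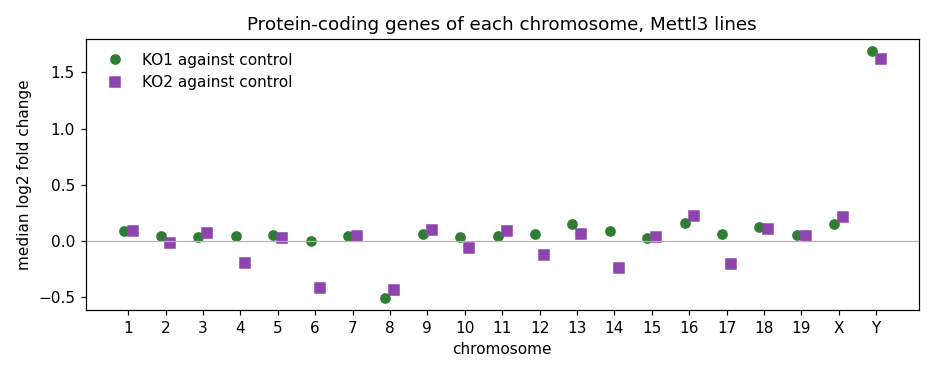
Median log2 fold change against the Mettl3 control of protein-coding genes on each chromosome, for KO1 and KO2, with library n = 2 per line. Chromosome 8 is at -0.51 and -0.44, and chromosome 6 at 0.00 in KO1 and -0.42 in KO2.

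The mean of both Mettl3 lines was compared with control for their average change, which 1 line alone can carry. Sp5 rose by 5.15 ± 0.24, Lef1 by 3.11 ± 0.25 and Wnt5b by 3.01 ± 0.13; Id1 (-3.50 ± 0.097), the heat shock gene Hspa1b (-2.77 ± 0.12), the keratin gene Krt19 (-2.62 ± 0.17), Meg3 (-1.97 ± 0.034), Rian (-1.80 ± 0.032), the germ cell helicase gene Ddx4 (-1.56 ± 0.10) and Malat1 (-0.56 ± 0.017) fell. Rian was at -2.72 in KO1 and -0.88 in KO2, and Meg3 at -3.08 and -0.85. Zfp981 (1.85 ± 0.041), Igf2bp2 (1.27 ± 0.060) and Atrx (1.252 ± 0.025) rose. Ythdc1 was lower, by a change of -0.54 ± 0.032. Mettl3 was lower by a change of -0.35 ± 0.068 (adjusted p = 7.82e-06; -0.10 in KO1, which did not pass, and -0.61 in KO2), which spike-in scaling turned to 0.02 (adjusted p = 0.844) and a test against a 1.2-fold change did not pass (adjusted p = 0.0912). The 2-cell-like list fell in 17 of 25 cases and rose in 0 (18 and 0 adjusted over the list alone; median -0.93, adjusted p = 6.37e-05, and 0.409 with an estimated correlation), with a median of -1.32 in KO1 but -0.45 in KO2, where it was not called (2 up and 10 down; adjusted p = 0.192) and turned to 0.12 when scaled to spike-ins (5 up and 3 down). Fibroblast feeder markers rose in 8 of 11 cases (the same adjusted over the list alone; median 0.65, adjusted p = 0.00299, and 0.484 with an estimated correlation), with a median of 1.18 in KO2 but 0.13 in KO1, where the list was not called (4 up and 2 down; adjusted p = 0.346). Also called were mitochondrial mRNAs (10 up and 0 down of 12), histones (37 and 2 of 61), housekeeping mRNAs (13 and 1 of 19) and ribosomal proteins (43 and 18 of 81). So were germline (1 up and 10 down of 18), trophoblast (1 and 8 of 12) and endoderm genes (1 and 10 of 18). None of these lists passed with an estimated correlation. For the mitochondrial, housekeeping and ribosomal protein lists, carry-over into the nuclear fraction and a change in the cells cannot be told apart here either. In all, 10769 genes changed, 5205 higher and 5564 lower, and 2440 by at least 2-fold; 6135 passed against a 1.2-fold change. Scaled to spike-ins, 10668 were higher and 2025 lower, with a median of 0.34.

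Of the genes called in both KO1 and KO2, 5850 moved the same way and 1122 the opposite way; at 2-fold or more, 1078 and 26, and against a 1.2-fold change 3036 moved the same way. Independent lists would share 2547 in the same direction, but both lines were compared with the same 2 control libraries. With 1 control library given to each line, a division chosen after seeing the data, 4696 and 4707 moved the same way in the 2 possible divisions and 1015 and 961 the opposite way, and the fold changes correlated by r = 0.417 and 0.421; both controls are of the same line. In 20 simulations of unchanged lines against shared controls, the calls shared in direction had a median of 0.5 and a maximum of 4, the covariance of fold changes across genes was 0.0422 against 0.3796 observed, and their correlation was r = 0.52 against 0.585 observed. The simulations drew all libraries from the control means, with the spread found between libraries of the same line. They hold no difference between lines, so they cannot show whether a control line that differs for other reasons gives the shared calls. The lines differed from each other in 10042 genes, 5332 higher in KO1 and 4710 lower, and 2406 by at least 2-fold; 5720 passed against a 1.2-fold change. Naive pluripotency genes were higher in KO1 than in KO2 in 22 of 25 cases and lower in 1 (the same adjusted over the list alone; median 0.52, adjusted p = 1.8e-07, and 0.139 with an estimated correlation), or 13 higher and 7 lower when scaled to spike-ins (median 0.14). Imprinted genes were lower in 19 of 28 cases and higher in 4 (20 and 4 adjusted over the list alone; median -0.93, adjusted p = 9.95e-05, and 0.139 with an estimated correlation). Fibroblast feeder markers were lower in KO1 in 8 of 11 cases, the same adjusted over the list alone (median -1.10, adjusted p = 0.000511, and 0.268 with an estimated correlation). The share of feeder cells in each line was not measured. Scaled to spike-ins, 1663 genes were higher and 10483 lower, with a median of -0.38.

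The Ythdc1 and Mettl3 effects were set side by side at 0 h, in libraries that share no control. Of the genes called in both cKO against control and the mean of the Mettl3 lines, 1286 moved the same way and 2223 the opposite way, 36.6% the same (Fisher's exact test, two-sided, odds ratio 0.342, p = 4.52e-54). The test takes genes as independent, which they are not, so its p does not measure the spread between libraries. The share moving the same way was 33.0% with KO1 alone and 42.1% with KO2 alone, and 22.6% at the 2-fold limit (53 the same way and 182 the opposite way). It was 11.3% when scaled to spike-ins, but that scaling moves most cKO calls lower (790 higher and 7571 lower). It moves most calls of the Mettl3 mean higher (10668 and 2025), so a low share follows from the scaling itself. Across the 16831 genes tested in both, which are not independent replicates, the fold changes had r = -0.16 and rho = -0.16. The fractions also differed in opposite directions. Reads outside genes per gene read were 1.21 in cKO and 1.06 in control at 0 h. In the Mettl3 experiment they were 0.637 in KO1 and 0.739 in KO2, against 0.748 in control. Whether such differences between nuclear fractions enter the opposite movement was not tested, so it need not reflect loss of the reader and the writer. The 2-cell-like list rose in cKO and fell in the Mettl3 mean, where it did not pass with an estimated correlation (adjusted p = 0.0136 in cKO and adjusted p = 0.409 in the mean) and was called in KO1 but not in KO2, and Malat1 rose by 0.71 and fell by 0.56.

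Gene reads per spike-in read, which compare counted RNA with the amount of spike-in, fell in control from 1276 (SD 27.2, n = 2) at 0 h to 909 (SD 2.89) at 3 h and 773 (SD 1.57) at 6 h. In libraries labelled cKO they were 1014 (SD 37.8) at 0 h, 3640 (SD 51.2) at 3 h and 535 (SD 8.74) at 6 h. The cKO 3 h libraries had spike-in shares of 0.0277% (95% Wilson interval 0.0269 to 0.0286) and 0.0272% (0.0265 to 0.0279), against 0.110% (0.108 to 0.111) in the first control library at 3 h. The ratio of cKO to control at 3 h was 4.01 (SD 0.0578). The Mettl3 control had 1804 (SD 33.9), KO1 2122 (SD 31.7) and KO2 2788 (SD 4.64). These values were not tested.

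**Figure D4:**
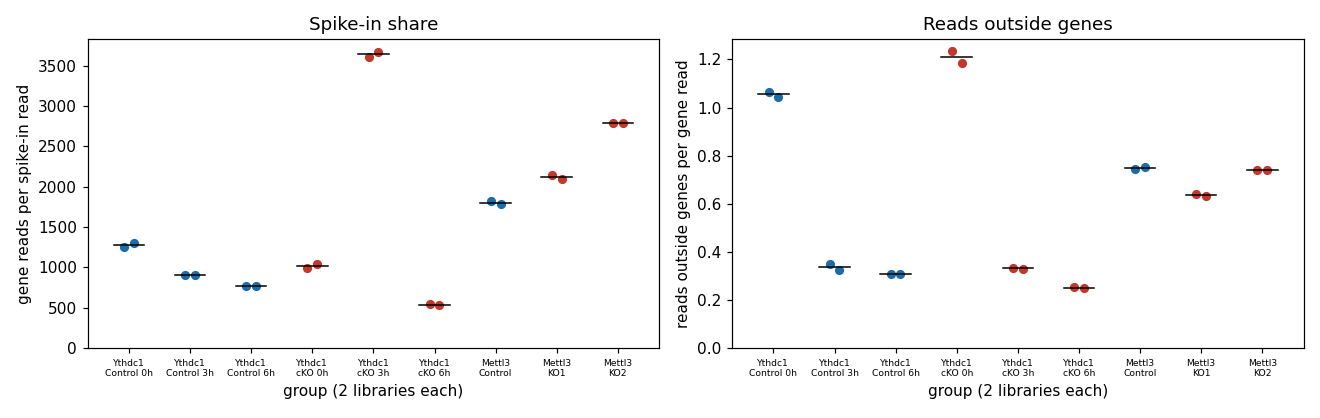
Gene reads per spike-in read (left) and reads outside genes per gene read (right) in each group; points are libraries, 2 per group, blue for control and red for cKO or KO, and lines are means. The cKO 3 h libraries stand at 3640 gene reads per spike-in read, against 909 in control at 3 h.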

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

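The tests of the spike-in share and of Ythdc1 RNA at 0 h were chosen after the result was seen, while those of chromosome 8 were written before.

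Both cKO 3 h libraries held 4.01 times as many gene reads per spike-in read as control at 3 h, and their reads outside genes per spike-in read stood at 1203 against 308 in control, a value from reads that enter no comparison of genes. Cytoplasmic RNA carried into these nuclear fractions is argued against as the sole cause. Reads outside genes per spike-in read rose by a factor of 3.91 (3.75 to 4.09 over pairs of libraries), where carry-over alone leaves them low. This factor moves with the spike-in share, so it cannot exclude some carry-over beside another cause. Mitochondrial genes took 3.54% of gene reads in cKO and 2.39% in control at 3 h, and 3.70% and 2.51% at 0 h. The factor of reads outside genes over that of gene reads, 0.977, cannot separate more sample RNA or less spike-in from a real rise. It holds no spike-in reads and is near 1 under both. A real rise of nuclear RNA in these cells is argued against by the design, since actinomycin D stops transcription. Even so, gene reads per spike-in read in cKO stood at 1014 (SD 37.8) at 0 h, 3640 (SD 51.2) at 3 h and 535 (SD 8.74) at 6 h. More sample RNA or less spike-in in both libraries was not measured directly. Housekeeping mRNAs scaled to spike-ins changed by -2.65 from 3 to 6 h in cKO and 0.04 in control, but this difference of -2.68 follows from the spike-in share itself and decides nothing.

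Genes of chromosome 8 were lower in both Mettl3 knockout lines than in the control line, with medians of -0.51 and -0.44. A bias by GC content or gene length is argued against, since genes of other chromosomes matched on both and on level had a median of 0.039 in KO1. A control line with more copies of chromosome 8 is a candidate explanation: against the Ythdc1 control, that line's chromosome 8 median lay 0.54 above its autosomes, with other autosomes from -0.51 (chromosome 11) to 0.25, while KO1 and KO2 stood at 0.01 and 0.15 (chromosome 11 at -0.52 and -0.40), and each of 3 parts of the chromosome was lower in both lines (-0.38 to -0.55). Loss of Mettl3 itself as the cause is argued against by the same values, since chromosome 8 in KO1 and KO2 was not below the Ythdc1 control. That control belongs to another experiment, from which chromosome 11 differed about as much, and no second Mettl3 control line was measured.

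Ythdc1 RNA at 0 h was not called lower in libraries labelled cKO with TMM scaling, but was at -0.44 and called lower when scaled to spike-ins (adjusted p = 2.49e-05), where the median of all genes was -0.35. A wrong label on these libraries is argued against: their difference from control at 0 h correlated with that at 6 h by r = 0.415 across genes, and 90.3% of the 1013 genes changed by at least 2-fold kept their sign. That a deleted part of the gene leaves the rest of its RNA to be counted cannot be told from these data, since counts cover the whole gene (-0.070). Changes in how fast Ythdc1 RNA is made were not tested.

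The changes over time differed between genotypes in 3422 genes at 6 h and 3476 at 3 h by the interaction test, and the Mettl3 lines differed in 10042 genes. Decay differences at 6 h, as log2 values, were -1.31 for Ythdc1, 3.26 for Hist1h2ah, 1.41 for Hist1h4h, 2.84 for Spry4, 2.25 for Zfp748, 1.26 for Zfp961, 1.29 for Fgf4, 0.87 for Dppa2, 1.48 for Snhg3, -1.38 for Neat1, -1.52 for Jun, -1.83 for Pck2, -1.47 for Snx29, -1.08 for Scarna6, 1.70 for mt-Nd1, 0.96 for mt-Cytb, 1.06 for Rpl31, -1.03 for Zc3h13, -0.96 for Col4a1 and 0.80 for Eda2r. List medians of that difference were 0.77 for histones, 0.34 for Zfp genes, 1.24 for mitochondrial mRNAs, 0.084 for ribosomal proteins and -0.30 for endoderm.

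Between KO1 and KO2 the list medians that passed the camera test were 0.52 for naive pluripotency, 0.42 for formative and primed pluripotency, 0.42 for housekeeping mRNAs, 0.25 for ribosomal proteins, 0.24 for histones, 0.20 for m6A machinery, 0.17 for Zfp genes, -0.70 for Hox clusters, -0.76 for mitochondrial mRNAs, -0.93 for imprinted genes, -1.10 for fibroblast feeder markers and -1.11 for the 2-cell-like list; when scaled to spike-ins, those of ribosomal proteins, histones, m6A machinery and Zfp genes turned negative, and those of formative and primed pluripotency and housekeeping mRNAs were 0.037 and 0.040. None of them passed with an estimated correlation. Reads outside genes per gene read, a measure outside the comparisons, stood at 1.21 in cKO at 0 h against 1.06 in control. In the Mettl3 experiment this measure was 0.748 in control, 0.637 in KO1 and 0.739 in KO2.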

How the results depend on the processing

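The tests without genes of some chromosomes, without the cKO 3 h libraries, with the 5 most abundant spike-ins and with the Mettl3 controls divided were chosen after seeing the data. Under the alternatives, 2870 values of named genes kept direction and call, 29 lost the call, 1 gained it and 9 changed sign, those of Mettl3, Ythdc1 or Rn7sk. Apart from Ythdc1 and Mettl3, the named genes were chosen as called in the same libraries. Their kept calls therefore say little about other called genes.

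A 2-fold limit gave 1013 (cKO at 0 h), 3506 and 5885 (control at 3 and 6 h), 4115 and 4959 (cKO), 409 and 648 (decay difference at 3 and 6 h), 2228 (KO1), 3380 (KO2), 2440 (mean), 2406 (KO1 against KO2) and 1078 (shared), as a stricter limit must. Against a 1.2-fold change the counts were 2324 (cKO at 0 h), 1433 and 1571 (decay difference), 5793, 7178, 6135 and 5720 (Mettl3) and 3036 (shared). Spike-in scaling gave 8361 genes for cKO at 0 h and 15997 for the decay difference at 3 h, and 8 lists in KO2; it turned Mettl3 to -0.10 (cKO at 0 h), 0.085 (KO1) and 0.019 (mean) and Rn7sk at 6 h to -0.0049. Library size alone gave 3 lists in KO2 and Mettl3 at 0.0080 in the decay difference at 6 h, with 0.0086 when nothing was filtered. Later decay of genes higher at 0 h, less that of the others, was -0.0081 and turned to 0.0056 at the 2-fold limit, 0.083 without a filter, where it passed the camera test, and 0.052 in 1 fit of all 18 libraries, which also gave 8 lists for the decay difference at 6 h. Linear time gave 41 genes, with the folds of named genes keeping their sign. Lists past the threshold with an estimated correlation and with fry numbered 1 and 14 (cKO at 0 h), 3 and 22 (control at 6 h), 1 and 12 (decay difference), 0 and 18 (KO1), 0 and 20 (KO2) and 0 and 16 (mean); KO2 had 2 without the genes of the chromosomes named. The cause was not tested, except that fewer or stricter tests follow from the limits.

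With each library left out in turn, counts ranged from 3486 to 4493 (cKO at 0 h), 8286 to 8982 and 10246 to 10937 (control at 3 and 6 h), 8954 to 9390 and 8622 to 10378 (cKO), 2423 to 3451 and 2494 to 3578 (decay difference), 8259 to 8757 (KO1), 9099 to 9868 (KO2), 9086 to 10295 (mean), 8078 to 8606 (KO1 against KO2) and 5048 to 5094 (shared). The same-direction share of Ythdc1 and Mettl3 calls ranged from 34.3% to 38.8%, the spike-in ratio from 3.97 to 4.05, and later decay from -0.0196 to 0.0171, turning to 0.0171 without replicate 2 of cKO at 0 h and to 0.0093 without replicate 2 of cKO at 6 h. Lists ranged from 7 to 11 (cKO at 0 h), 11 to 12, 4 to 6 (decay difference), 10 to 11 (KO1), 3 to 5 (KO2) and 8 to 9 (mean). Ythdc1 at 0 h ranged from -0.20 to 0.045 and Mettl3 in the decay difference from -0.27 to 0.015, both turned without replicate 2 of cKO at 0 h; Mettl3 in KO1 ranged from -0.20 to 0.0025, turned without replicate 1 of the Mettl3 control. The lone library is then assumed to vary like the other groups.

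Replicate number as a block left the direction and call of each named gene as they were and moved no count by over 1.5 times, with 5481 genes for cKO at 0 h, 3715 for the decay difference at 6 h, 9891 for KO1 and 10952 for KO2. Leaving out the cKO 3 h libraries moved no count by over 1.5 times. Depth limits genes near the filter; 1 cKO 6 h library had 4950973 gene reads.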

Other observations

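The correlations given here were chosen after the result was seen, and no explanation is offered.

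Xist, the RNA that coats the inactive X chromosome, stood at 287 CPM (SD 18.3, n = 2) in the Mettl3 control, 311 (SD 4.44) in KO1 and 189 (SD 4.74) in KO2, but at 0.223 (SD 0.00871) in the Ythdc1 control at 0 h. Y-linked Ddx3y stood at 35.6 (SD 0.426), 115 (SD 4.60) and 109 (SD 3.12) in the Mettl3 lines and at 72.1 (SD 3.54) in the Ythdc1 control, so reads of both were present in each Mettl3 line. Col1a1 was at 103 (SD 2.49), 96.3 (SD 0.130) and 272 (SD 3.09) in the Mettl3 control, KO1 and KO2, against 1.70 (SD 0.723) in the Ythdc1 control, and Col3a1 at 11.7, 12.6 and 29.1 against 0.0924. The imprinted gene Rtl1 was at 101 (SD 2.58), 17.9 (SD 1.37) and 52.7 (SD 1.75) in the Mettl3 lines and at 0.0542 (SD 0.0766) in the Ythdc1 control. Relative to the autosomes of the Ythdc1 control, the median of chromosome 6, which holds Mest, Stra8 and Col1a2, was 0.25 in the Mettl3 control, 0.25 in KO1 and -0.14 in KO2, and that of chromosome 14, which holds Mettl3, was -0.091, -0.076 and -0.34; whether copy number enters the changes of these genes in KO2 was not tested. Gm26917 took the most gene reads of any gene in each library without the drug, from 53520 (SD 2400) CPM in control at 0 h to 3161 (SD 401) at 3 h and 5406 (SD 3.04) at 6 h.

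The cKO effect at 0 h persisted under the drug: across genes it correlated by r = 0.506 with that at 3 h and r = 0.415 with that at 6 h, and by 0.775 and 0.701 among the 1013 genes changed by at least 2-fold at 0 h. These genes are not independent replicates, and libraries at the 3 times share no library. With TMM scaling, 7695 genes differed between cKO and control at 3 h (3986 higher and 3709 lower), and 7591 at 6 h (3531 and 4060). These counts were not made with spike-in scaling, where the ratio of cKO to control at 3 h was 4.01.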
